A study of Homo sapiens with 10 samples.

How the data were processed

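Total RNA from 10 samples of the human prostate cancer cell lines DU145 and LNCaP was measured on Affymetrix expression arrays, 1 array per sample. Per the labels' protocols, cells were transduced with a reporter vector called EOS, in which the OCT4 and SOX2 enhancers drive GFP and a puromycin resistance gene, and grown in puromycin. Control cells carried a vector with the same genes under the ubiquitous PGK promoter. RNA was isolated with a spin column kit and biotin-labelled amplified RNA was prepared, per the labels' protocols. Each line had 2 PGK arrays, 2 EOS arrays and 1 array of EOS cells treated with ribavirin, which the labels tie to EOS number 2. Nothing in the labels says that arrays 1 and 2 of a group came from separately selected cultures, so p-values measure the spread between these arrays, which may be technical.

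The deposited values were probe set intensities on a linear scale. The submitters' processing notes name MAS5 and affy without versions or roles, and the background correction and scaling target were not given in the sources used here. Detection calls were not used here. The 4 arrays numbered 1 had a 2% trimmed mean of 500 each, and the 6 arrays numbered 2 had trimmed means from 96.56 to 126.5, so that the deposited intensities were on different scales. The ratio of the 3' to the 5' probe set of ACTB, a sign of RNA length after amplification, was 1.236 to 1.511 in the arrays numbered 1 and 3.204 to 3.993 in those numbered 2. The same ratio for GAPDH was 0.9585 to 1.06 and 1.092 to 1.216. The numbers thus differ in deposited scale and RNA end ratio, for a reason the labels do not give. Each PGK and EOS group spans both numbers equally, while both ribavirin arrays lie in number 2.

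The design fixed before the data were examined assumed log2 values as deposited. Because the intensities were linear and on different scales, each array was instead scaled to a 2% trimmed mean of 500 and transformed as log2(intensity + 16), which understates the change of dim genes. The unscaled values were kept as an alternative for the EOS and line comparisons only, since the ribavirin controls mix both deposited scales. Unscaled, the median change of all genes for EOS against PGK in DU145 moved from -0.02 to -0.18. List medians are also given relative to it, whereas single genes and counts on the unscaled values are not corrected for it. Without the replicate block, the unscaled fit also keeps the difference in deposited scale between arrays of a group in the spread. A low count in that fit is thus no sign of absent change.

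Of 54675 probe sets, 62 were array controls and were left out. In the platform annotation 41097 probe sets had 1 gene symbol, 1801 had several and 11777 had none. Of those with 1 symbol, 41043 matched a current gene by Entrez identifier, and the match changed 0 symbols. Probe sets above the median of the array in at least 2 of the 10 arrays were kept, which left 33451. Of these, 27494 had 1 gene, and the probe set with the highest mean was taken for each gene, giving 14313 genes. Another probe set was kept for 7226 genes, and where it differed in sign for a gene named by the rule below, the largest such value is stated. OCT4 (POU5F1) was measured only by a probe set shared with related sequences, and NANOG was not analysed here.

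Differences were tested with limma 3.58.1 in R 4.3.3: cell means of the 6 groups, 4 residual degrees of freedom, empirical Bayes moderation with an intensity trend, and Benjamini-Hochberg adjustment at 0.05. All 10 arrays shared the estimate of the spread, so the single ribavirin array of each line was assumed to vary like the other groups. Each value after ± is a standard error from this shared, moderated spread, not from the arrays of the compared groups alone. The comparisons were EOS against PGK in each line, their mean and their difference, ribavirin against EOS in the same 4 forms, and LNCaP against DU145 among the PGK controls as a check of the labels. With 2 arrays against 2, an exact two-sided permutation test of a single gene cannot go below p = 0.333. The number of arrays limits the precision of every value.

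The replicate numbers paired the arrays: deviations from the group mean correlated between PGK and EOS arrays of the same number, with r = 0.123 in DU145 and r = 0.484 in LNCaP across genes. A fit with line and number as a block was therefore run beside the unblocked one.

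A set of 27 gene lists, among them markers of cell types other than epithelium, was fixed before the data were examined. The 26 lists with at least 3 tested genes were tested with limma's camera at a preset correlation of 0.01, with the adjustment made over the lists of a contrast. Camera with an estimated correlation and fry were run beside it. The estimated form called 0 lists in every comparison, also between the lines. For interferon-stimulated genes in DU145 the estimate, 0.0111, was close to the preset, yet the camera p went from 4.31e-07 to 0.00741. A call lost in that form is thus not by itself a sign of correlation between genes or of absent change. Fry asks whether the genes of a list move one way on balance and does not compare the list with other genes. Within each list, genes were also adjusted over the list alone. No adjustment was made across the lists there, so some genes can pass by chance.

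Named genes followed a rule fixed before the data were examined. Genes past the threshold came first. Where too few passed in a direction, the genes of smallest p were named, up to 5 each way, and are stated not to pass. SOX2, KLF4, MYC, CD44, KLK3, TMPRSS2, VIM, CDH1, EIF4E, IMPDH1, IMPDH2, CDKN1A and MDM2 were reported for EOS in each line and for ribavirin over the mean. List members given as examples were chosen after their values were seen.

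The fits were tested on simulated arrays with 200 of 14313 genes changed, in 5 runs. For EOS against PGK in DU145, 10% of genes changed 2-fold and 50.6% of those changed 4-fold were recovered, with 3.4 other genes called on average. For the mean of both lines the shares were 32.8% and 75.6%, with 4.8 other genes called. For ribavirin, mean of both lines, they were 23% and 62%, with 3.6 other genes called. For the DU145 contrast, 1 of 520 tests of unchanged simulated lists was called at the preset correlation, and a list raised 2-fold was called in 20 of 20 runs. These simulations drew genes independently, so they do not test the preset correlation. They also drew arrays independently, without any pairing by number, so the shares recovered and the other genes called may differ in the real arrays.

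Alternatives chosen before the data were examined were pseudocounts of 1 and 64, no filter or a 75th percentile filter, quantile normalization, the mean of a gene's probe sets, all probe sets, moderation without trend or robust, an additive fit over lines, only the 4 arrays compared, EOS 2 as the sole ribavirin control, the replicate block, and each of the 10 arrays left out in turn. The unscaled values, the replicate number as a batch term, and the ribavirin comparison restricted to number 1 controls were added after the data had been seen. Correlations between contrasts that share arrays were set beside 100 simulated draws with no effect, in which all arrays were independent of each other. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.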

Results

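Gene expression was measured in DU145, an androgen-independent prostate cancer line from a brain metastasis, and in LNCaP, an androgen-responsive line from a lymph node metastasis. The series compared cells selected in puromycin with the EOS reporter, which is driven by OCT4 and SOX2 enhancers, with cells carrying a PGK-driven control vector. A further array in each line measured EOS cells number 2 after ribavirin, a guanosine analogue known as an inhibitor of IMP dehydrogenase and reported to act on the translation factor eIF4E. DU145 and LNCaP each contributed 2 PGK, 2 EOS and 1 ribavirin array, and 14313 genes were tested. Principal component 1 held 76.3% of the variance and separated the lines. Component 2 held 8.14% and separated the LNCaP arrays numbered 1, at 46.5 and 48, from those numbered 2, at -21.2 to -37.4. The LNCaP PGK array numbered 2 stood apart at -53.3 on component 3, which held 4.21%.

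**Figure D1:**
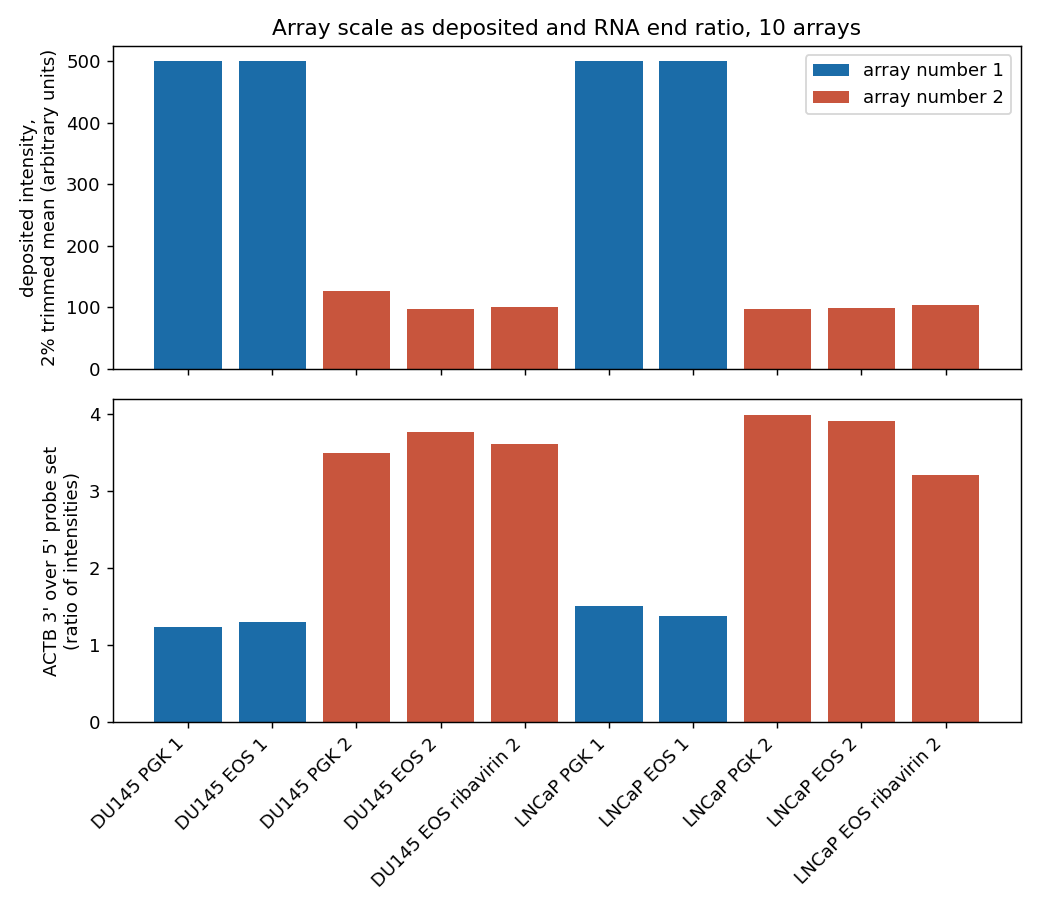
Upper bars give the 2% trimmed mean of the deposited intensity of each of the 10 arrays in arbitrary units, and lower bars give the ratio of the 3' to the 5' ACTB probe set, coloured by array number. The 4 arrays numbered 1 sit at 500 with ratios of 1.236 to 1.511, and the 6 numbered 2 sit at 96.56 to 126.5 with ratios of 3.204 to 3.993.

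The line labels were checked first, among the PGK controls. The check rests on androgen-responsive genes, for which LNCaP is known, and does not test the identity of DU145 itself. Genes of prostate luminal cells that respond to androgen were far higher in LNCaP. KLK3, which encodes prostate-specific antigen, was higher by 9.34 ± 0.25 log2 (SE, 2 arrays per line; 650-fold, limma adjusted p = 2.12e-07). KLK2 was higher by 8.61 ± 0.42, TMPRSS2 by 7.21 ± 0.38 and HOXB13 by 5.99 ± 0.32. Of the 19 tested genes of that list 15 passed the threshold as higher, and 15 when adjusted over the list alone. Epithelial junction genes followed, with 12 of 17 passing as higher (13 adjusted over the list alone). Among them CDH1, the adhesion protein E-cadherin, was higher by 7.58 ± 0.30 and GRHL2, an epithelial transcription factor, by 6.27 ± 0.24. DU145 had more of CD44, a cell surface receptor used as a stem cell marker (LNCaP minus DU145 -6.19 ± 0.28, 73.1-fold lower), and of ZEB1, a repressor of epithelial genes (-6.06 ± 0.40). It also had more of GSTP1, a detoxifying enzyme (-5.98 ± 0.38), and of the intermediate filament gene VIM (-3.45 ± 0.49). Between the lines 4733 genes passed, 2172 higher and 2561 lower in LNCaP. The count was 2595 without DU145 PGK 1, 2497 without DU145 PGK 2 and 57 on the unscaled values. On the unscaled values each PGK group holds arrays of both deposited scales, which widens the spread. The low count there is therefore no sign of a weaker difference between the lines. The luminal list shifted by a median of 3.68 (camera adjusted p = 1.22e-09) and the epithelial junction list by 4.53 (adjusted p = 4.53e-09). The adjusted p was 0.249 with an estimated correlation for both. Of the 26 lists 12 were called at the preset correlation, 0 with an estimated one and 16 by fry.

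In DU145, interferon-stimulated genes, the antiviral set induced by interferon signalling, were lower in EOS-selected cells than in PGK controls. The median of the 19 tested genes was -0.49 log2 and 18 of 19 lay below 0. Among them were IFIT2 at -0.89 ± 0.53, ISG15 at -0.46 ± 0.19 and IFITM3 at -1.75 ± 0.81 (SE from the spread shared by all groups, 2 arrays per group). IFITM3 differed by -3.79 in array pair 1 and by 0.28 in pair 2. The list fell in camera (adjusted p = 1.12e-05; adjusted p = 0.193 with an estimated correlation), with medians of -0.79 in pair 1 and -0.27 in pair 2. Epithelial junction genes fell as a list, with a median of -0.37 and 14 of 17 below 0 (adjusted p = 0.000701; adjusted p = 0.714 with an estimated correlation). Among the PGK controls this list was lower in DU145 than in LNCaP, by a median of 4.53. Some of its genes may therefore be dim in DU145, which leaves the size of their change uncertain. CDH1 was at -0.89 ± 0.30, the adhesion molecule EPCAM at -0.96 ± 0.25 and the keratin KRT19 at -0.99 ± 0.49. That fall lay in pair 1, with a median of -1.02 against -0.13 in pair 2, and its adjusted p was 0.363 without PGK 1 and 0.931 without EOS 1.

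Genes of cell division and ribosome production were slightly higher in the DU145 EOS cells. The nucleolus and ribosome biogenesis list rose by a median of 0.17 with 15 of 16 genes above 0 (adjusted p = 0.000264; adjusted p = 0.582 with an estimated correlation). UTP20, part of the machinery that processes the small subunit rRNA, was at 0.48 ± 0.21. The G2/M and mitosis list rose by 0.14 with 19 of 20 above 0 (adjusted p = 0.000508; adjusted p = 0.714 with an estimated correlation). Without EOS 1 the adjusted p of these lists was 0.473 and 0.377. Of the 20 genes of the pluripotency list 9 were tested, without OCT4 and NANOG, so the list is no direct readout of the reporter. It rose by a median of 0.25 with 8 of 9 tested genes at or above 0 (adjusted p = 0.0198; adjusted p = 0.516 with an estimated correlation; fry adjusted p = 0.0454). Its members were close to their errors: SOX2 0.43 ± 0.44, KLF4 -0.01 ± 0.34, MYC 0.21 ± 0.16, ESRRB 0.56 ± 0.37 and GDF3 0.58 ± 0.51. Its adjusted p was 0.0775 without EOS 1, 0.0814 without PGK 2 and 0.122 without EOS 2. A probe set shared by OCT4 and its related sequences differed by 0.08 ± 0.56 in DU145 and 0.31 ± 0.56 in LNCaP. Its signal cannot be assigned to OCT4 itself. Fibroblast markers rose by a median of 0.91 with 3 of 5 genes above 0 (adjusted p = 0.047; adjusted p = 0.787 with an estimated correlation), led by POSTN at 2.35 ± 1.11 and COL3A1 at 1.78 ± 0.81. The rise lay in pair 2, at 1.97 against -0.15 in pair 1 (adjusted p = 0.962 without EOS 2 and 0.168 without PGK 1). On the unscaled values the median was 0.31, or 0.49 relative to the median of all genes. The 6 leukocyte markers had a median of 0.18 and were not called (adjusted p = 0.243). Of all 26 lists 6 were called in DU145 and 8 with the replicate block, which added the eIF4E target list (blocked adjusted p = 0.0327; adjusted p = 0.714 with an estimated correlation) and heat shock genes (blocked adjusted p = 0.0337; adjusted p = 0.809 with an estimated correlation).

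Among single genes in DU145, those of smallest p included CCL20, a chemokine that attracts lymphocytes and dendritic cells, at -3.66 ± 0.60 (-3.39 and -3.94 in the pairs). They also included PMCH, the precursor of melanin-concentrating hormone, at 2.39 ± 0.47. In the PGK arrays PMCH, at 4.28 and 4.27, lay near the floor of 4 that the pseudocount sets, so the size of its difference is not determined (4.31 with a pseudocount of 1 and 1.15 with a pseudocount of 64). CALD1, an actin-binding protein, was at -0.95 ± 0.16, and its 6 other probe sets also lay below 0. The glutaminyl cyclase QPCT was at -2.66 ± 0.54, the cathepsin CTSF at -1.44 ± 0.28 and YPEL3 at -2.45 ± 0.44, with another YPEL3 probe set at 0.15. MATN1 was at 2.02 ± 0.47, SEMA5B at 1.68 ± 0.43, VPS13A-AS1 at 1.85 ± 0.46 and DUSP8 at 1.54 ± 0.33, with another DUSP8 probe set at -0.27. None of these passed the threshold over all genes (limma adjusted p = 1 for each). Adjusted over the list alone, CCL20 passed in the inflammatory list (adjusted p = 0.00353) and the Wnt target RNF43, at -1.62 ± 0.40, in its list (adjusted p = 0.0462). The remaining genes fixed in advance were CD44 at 0.08 ± 0.28, KLK3 at 0.14 ± 0.25, TMPRSS2 at -0.48 ± 0.38, VIM at 0.27 ± 0.49, EIF4E at 0.00 ± 0.19, IMPDH1 at 0.15 ± 0.22, IMPDH2 at 0.01 ± 0.18, CDKN1A at -0.10 ± 0.36 and MDM2 at -0.05 ± 0.26. Other probe sets went the other way for CD44 (-0.11), KLK3 (-0.22), TMPRSS2 (0.43) and MDM2 (0.16), and EIF4E had one at 0.28. KLK3 and TMPRSS2 were far lower in DU145 than in LNCaP among the PGK controls, so their values here may lie near the floor set by the pseudocount. limma called 0 of 14313 genes, with 226 at an unadjusted p under 0.05 where chance gives 716, and 0 with the replicate block, with 480. The unblocked fit keeps differences between the array numbers in the spread that both lines share. A count below 716 is therefore no sign of less change than chance. On the unscaled values it called 0 without and 34 with the block, neither corrected for the median change of all genes there, -0.18.

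In LNCaP, EOS-selected cells had more RNA of genes induced by low oxygen and of glycolysis. That list rose by a median of 0.54 with 17 of 19 genes above 0 (camera adjusted p = 6.47e-06; adjusted p = 0.399 with an estimated correlation). Its members included NDRG1 at 1.04 ± 0.31, the glycolytic regulator PFKFB3 at 0.78 ± 0.23, the aldolase ALDOC at 1.12 ± 0.47 and the angiogenic factor VEGFA at 0.70 ± 0.29. Its adjusted p was 0.205 without EOS 1. Mesenchymal genes rose by a median of 0.79 with 12 of 14 above 0 (adjusted p = 0.00464; adjusted p = 0.333 with an estimated correlation). The surface glycoprotein THY1 was at 1.63 ± 0.55 and the matrix protease MMP2 at 1.21 ± 0.47, while VIM was at 0.30 ± 0.49. Relative to the median of all genes the mesenchymal list was at 0.74, and at 0.49 on the unscaled values. Interferon-stimulated genes rose by 0.51 with 17 of 19 above 0 (adjusted p = 0.00511; adjusted p = 0.333 with an estimated correlation). IFIT3 was at 0.78 ± 0.40 and IFITM1 at 2.90 ± 1.06, of which pair 1 gave 0.28 and pair 2 gave 5.51. Without PGK 1, EOS 1 or EOS 2 the adjusted p of that list was 0.0674, 0.062 and 0.0584. The p53 target list rose by 0.27 with 15 of 19 above 0 (adjusted p = 0.0294; adjusted p = 0.399 with an estimated correlation), a call lost without EOS 1 (adjusted p = 0.354) or PGK 2 (0.527). Its stress genes GADD45A and GDF15 were at 0.71 ± 0.21 and 0.82 ± 0.28, whereas the cell cycle inhibitor CDKN1A was at -0.17 ± 0.36 and MDM2 at -0.36 ± 0.26.

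The remaining lists called in the LNCaP EOS cells fell, with no member gene past the threshold over all genes. Nucleolus and ribosome biogenesis genes fell, with a median of -0.38 and 14 of 16 below 0 (adjusted p = 5.5e-06; adjusted p = 0.333 with an estimated correlation). The ribosome assembly factors RRS1 and NOP2 were at -0.85 ± 0.25 and -0.77 ± 0.25. The medians were -0.24 in pair 1 and -0.37 in pair 2, and the call held with each of the 10 arrays left out. G2/M and mitosis genes fell, with a median of -0.21 and 16 of 20 below 0 (adjusted p = 0.000104; adjusted p = 0.399 with an estimated correlation). Histone genes fell, with a median of -0.37 and 9 of 10 below 0 (adjusted p = 0.0016; adjusted p = 0.399 with an estimated correlation). The ATF4 and unfolded protein response list fell, with a median of -0.23 (adjusted p = 0.00646; adjusted p = 0.48 with an estimated correlation), a call lost without EOS 1 (adjusted p = 0.919) or PGK 2 (0.603). G1/S and replication genes fell, with a median of -0.14 (adjusted p = 0.0122; adjusted p = 0.639 with an estimated correlation). Of all 26 lists 9 were called in LNCaP, only the nucleolus list without EOS 1 and 3 without PGK 2, the array that stood apart on component 3. Without PGK 2 the G1/S list turned direction (adjusted p = 0.694), and the adjusted p of the G2/M list was 0.301 and that of the histone list 0.504.

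ENO2, the neuronal enolase used as a neuroendocrine marker, led the single genes in LNCaP, at 3.12 ± 0.51 (8.69-fold, with 2.64 and 3.60 in the pairs). It passed only when adjusted over its list of 4 tested genes alone (limma adjusted p = 0.000875). FOS, an immediate early transcription factor, was at 2.71 ± 0.53. The myosin light chain MYL9 was at 1.79 ± 0.31, with another probe set at -0.67, the matrix protein TINAGL1 at 1.93 ± 0.34 and the potassium channel KCNH2 at 1.81 ± 0.33. On the lower side were FLJ40288 at -2.34 ± 0.56, MAT2A, which makes S-adenosylmethionine, at -0.86 ± 0.23, and GTF2F2, a subunit of a general transcription factor, at -0.86 ± 0.23. COA7 was at -0.85 ± 0.22 and the nucleolar protein NIFK at -0.67 ± 0.17. TUBA1A, a tubulin, at 1.53 ± 0.33, also passed adjusted over the list alone (adjusted p = 0.0187). Androgen-responsive genes gave KLK3 at 0.10 ± 0.25 and TMPRSS2 at 0.94 ± 0.38, and CD44 was at -0.70 ± 0.28. Values for the other genes fixed in advance were SOX2 -0.39 ± 0.44, KLF4 0.35 ± 0.34, MYC 0.11 ± 0.16, CDH1 0.16 ± 0.30, EIF4E -0.24 ± 0.19, IMPDH1 0.15 ± 0.22 and IMPDH2 -0.17 ± 0.18. Other probe sets went the other way for CD44 (0.85), SOX2 (0.24), EIF4E (0.26) and MDM2 (0.08). limma called 0 genes (adjusted p = 0.999 for those named), with 596 at an unadjusted p under 0.05, and 0 with the replicate block, with 1297. On the unscaled values it called 0 without and 51 with the block. Without PGK 1 limma called 3 genes, BCHE at 2.62, MAF at 5.37 and MET at -3.56 (adjusted p = 0.0303). Without EOS 1 it called 4, HSD17B11 at 2.47, ITPRID2 at 2.84, MXRA7 at 1.93 and RTN2 at 3.54 (adjusted p = 0.0367). These genes were named after their values were seen, and the array left alone was assumed to vary like the other groups.

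**Figure D2:**
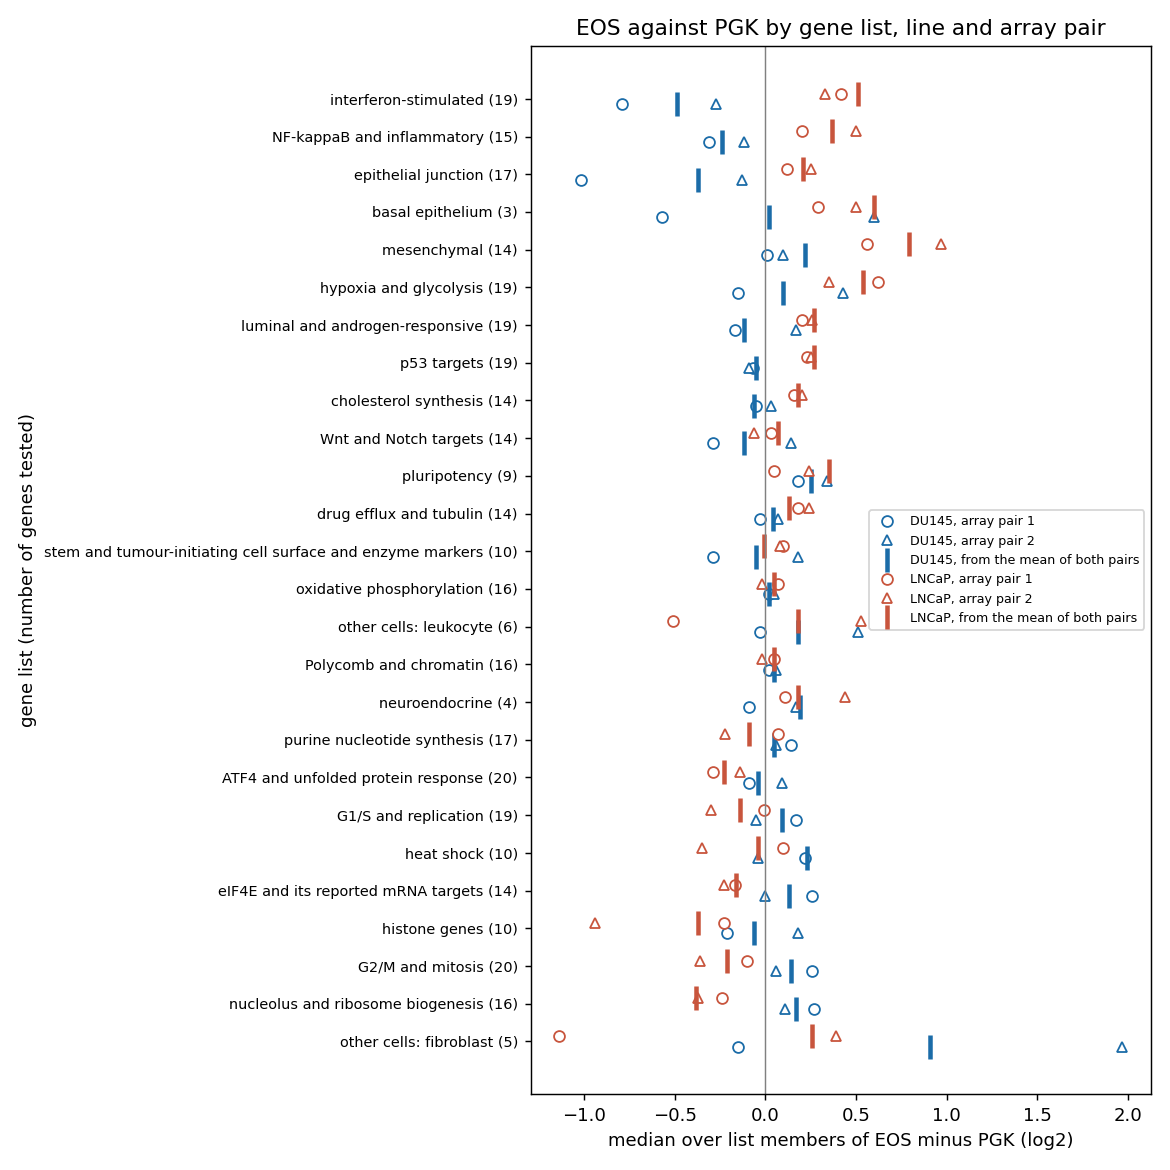
Each line of the plot is a gene list with the number of genes tested, and the horizontal axis is the median over its genes of EOS minus PGK in log2, with circles for array pair 1, triangles for pair 2 and bars for the median from both pairs. The interferon-stimulated list lies at -0.79 and -0.27 in the DU145 pairs and at 0.42 and 0.33 in the LNCaP pairs, and the nucleolus list at 0.27 and 0.11 against -0.24 and -0.37.

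Over the mean of both lines, hypoxia and glycolysis genes rose by a median of 0.24 with 16 of 19 above 0 (adjusted p = 1.58e-05; adjusted p = 0.691 with an estimated correlation), although the DU145 pairs gave -0.15 and 0.43. The pluripotency list rose by 0.19 with 9 of 9 above 0 (adjusted p = 0.00815; adjusted p = 0.436 with an estimated correlation; fry adjusted p = 0.0216). Its largest values were in LNCaP, where GDF3, a growth factor of the TGF-beta family, was at 1.25 ± 0.51 and the transcription factor TFCP2L1 at 1.31 ± 0.40. In LNCaP itself camera did not call the list, with a median of 0.35 and 7 of 9 above 0 (adjusted p = 0.106; adjusted p = 0.399 with an estimated correlation; blocked adjusted p = 0.141), while fry, which does not compare it with other genes, gave an adjusted p = 0.0294. Mesenchymal genes rose by 0.45 (adjusted p = 0.0162; adjusted p = 0.436 with an estimated correlation). The 4 neuroendocrine genes rose by a median of 0.25 and a mean of 0.52 (camera adjusted p = 0.0445, and 0.518 with an estimated correlation). Among them only ENO2, at 1.45 ± 0.36, had an unadjusted limma p under 0.05. The call may rest on that 1 gene, and the list was not tested without it. Histone genes fell, with a median of -0.23 (adjusted p = 0.0155; adjusted p = 0.691 with an estimated correlation), and so did the ATF4 list, at -0.10 (adjusted p = 0.0162; adjusted p = 0.793 with an estimated correlation). Without LNCaP EOS 1 none of the 6 lists was called, and the adjusted p of the pluripotency list was 0.0994. Without LNCaP PGK 2 the neuroendocrine, histone and ATF4 lists were not called. With each of the 10 arrays left out in turn, DU145 arrays among them, the neuroendocrine list lost its call in 5 cases. The histone and ATF4 lists lost it in 4 each and the mesenchymal list in 2. FOXD1, a forkhead transcription factor, was at 0.93 ± 0.22, from 0.67 to 1.30 in the 4 pairs. CCL20 was at -2.30 ± 0.43, JAKMIP1 at -1.43 ± 0.35, POLL at -1.46 ± 0.37, GTF2F2 at -0.65 ± 0.16 and CALD1 at -0.53 ± 0.12, with another CALD1 probe set at 0.14. On the higher side PMCH was at 1.43 ± 0.33, ENO2 at 1.45 ± 0.36, FOS at 1.44 ± 0.37 and the protease PRSS8 at 0.93 ± 0.23. limma called 0 genes for the mean, with 292 at an unadjusted p under 0.05 (0 and 693 with the block). On the unscaled values it called 0 without and 3 with the block.

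The EOS changes differed between the lines in several lists. The test of the difference, LNCaP minus DU145, called 11 of 26 lists, 6 without DU145 EOS 1 and 7 without LNCaP EOS 1 or without LNCaP PGK 2. With the replicate block it called 14, adding luminal and androgen-responsive genes (blocked adjusted p = 0.0106; adjusted p = 0.625 with an estimated correlation), mesenchymal genes (blocked adjusted p = 0.0106; adjusted p = 0.497 with an estimated correlation) and p53 targets (blocked adjusted p = 0.0139; adjusted p = 0.512 with an estimated correlation). Nucleolus and ribosome biogenesis was at -0.56 with 15 of 16 genes lower in LNCaP (adjusted p = 1.11e-08; adjusted p = 0.281 with an estimated correlation). G2/M and mitosis was at -0.37 with 19 of 20 lower (adjusted p = 2.02e-07; adjusted p = 0.497 with an estimated correlation). Interferon-stimulated genes were at 0.97 with 19 of 19 higher (adjusted p = 1.08e-06; adjusted p = 0.164 with an estimated correlation). These 3 calls held with each of the 10 arrays left out. The ENO2 difference, named after its value was seen, was 3.34 ± 0.72 (limma adjusted p = 1). No gene passed: limma called 0, with 464 at an unadjusted p under 0.05, and 0 with the block, with 1032 (82 with the block on the unscaled values). Across all genes, which are not independent replicates, the EOS changes of the lines correlated with r = -0.0409 (Spearman -0.0673). Unchanged simulated groups ranged from -0.0491 to 0.0424, but were drawn without the pairing of arrays by number, so this range decides nothing. Without DU145 EOS 1 r was 0.036. Between the array pairs of a line the correlation was 0.00913 in DU145 and 0.0827 in LNCaP.

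Ribavirin was compared with EOS cells in both lines, with 1 treated array each. IMPDH2, an IMP dehydrogenase, the enzyme that ribavirin is known to inhibit, was at 0.59 ± 0.15 over the mean of both lines (1.51-fold) and stood 1.68-fold above EOS 2 in DU145 and 1.23-fold above it in LNCaP. IMPDH1 was at 0.05 ± 0.19, EIF4E at 0.15 ± 0.17, and the purine nucleotide synthesis list had a median of 0.01 with 9 of 17 genes above 0. CAPN10, a calpain protease, was at -2.50 ± 0.51, a size that its dim treated arrays leave undetermined (-4.21 with a pseudocount of 1, -1.26 with 64). SH3D21 was at 1.93 ± 0.42, with 1.44 and 2.37. PTGER1, a prostaglandin receptor, was at 1.49 ± 0.34, with other probe sets at 0.01 and -0.01, RIIAD1 at 1.62 ± 0.45 and RPH3A at 1.39 ± 0.41. ACAD10 at -1.19 ± 0.27, ITPKB at -1.02 ± 0.24 and OXER1 at -1.28 ± 0.33 differed from EOS 2 in 1 line each, with other ACAD10 probe sets at 0.58 and 0.23, and LOC101929536 was at -1.30 ± 0.33. KLK3 was at -0.70 ± 0.22, TMPRSS2 at 0.66 ± 0.33, CD44 at -0.38 ± 0.24 and SOX2 at 0.30 ± 0.38. KLF4 was at 0.02 ± 0.30, MYC at -0.01 ± 0.14, VIM at 0.10 ± 0.43, CDH1 at 0.43 ± 0.26, CDKN1A at -0.33 ± 0.31 and MDM2 at -0.07 ± 0.23. Other probe sets went the other way for KLK3 (0.33), CD44 (0.60), SOX2 (-0.29), CDH1 (-0.28), MDM2 (0.42) and KLF4 (-0.89). Both ribavirin arrays are of number 2, while their controls hold both numbers. limma called 0 genes for the mean (adjusted p = 1 for those named), with 253 at an unadjusted p under 0.05, and 0 with the block, with 341. In DU145, LNCaP and their difference it also called 0, with 250, 289 and 222 at that level (0 with the block, with 364, 405 and 335).

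In DU145 after ribavirin, with 1 treated array assumed to vary like the other groups, Wnt and Notch targets rose by a median of 0.46 with 13 of 14 above 0, led by RNF43 at 1.44 ± 0.49 (adjusted p = 0.00917; adjusted p = 0.818 with an estimated correlation). G1/S and replication genes fell, with a median of -0.20 and 16 of 19 below 0 (adjusted p = 0.00691; adjusted p = 0.818 with an estimated correlation). The eIF4E target list fell as well, with a median of -0.20 and 12 of 14 below 0, including the glutamine transporter SLC1A5 at -0.96 ± 0.34 (adjusted p = 0.00691; adjusted p = 0.818 with an estimated correlation). The 3 calls rest on EOS 1, an array of the other number: without it their adjusted p was 0.406, 0.698 and 0.489. Without EOS 2 in DU145, 8 lists were called in DU145 and 7 over the mean. With the replicate block the 3 DU145 lists were called as well, still with 1 treated array. In LNCaP and over the mean of both lines camera called 0 of 26 lists, and 2 each with the replicate block. These were G1/S and replication (blocked adjusted p = 0.0175 in LNCaP and 0.000552 for the mean) and the ATF4 list (0.00134 and 0.0311). The smallest adjusted p with an estimated correlation was 0.969 in LNCaP and 0.976 for the mean.

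Ribavirin and EOS changes, mean of both lines, correlated with r = -0.196 across genes, with a covariance of -0.019 (r = 0.018 without LNCaP PGK 2 and -0.543 without LNCaP EOS 2). The EOS arrays enter both changes with opposite sign, and unchanged simulated groups gave -0.408, from -0.45 to -0.357, with a covariance of -0.0563. These groups were drawn without the pairing of arrays by number, so their range is no measure of no effect here. With the EOS arrays split between the changes, r was -0.00954 and the covariance -0.00112, against 0.000503 (-0.0683 to 0.041) and 0.000106 in simulated groups. That range was drawn in the same way. Since the EOS change barely correlated between the array pairs of a line (0.00913 in DU145 and 0.0827 in LNCaP), a split r near 0 decides nothing about a reversal.

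**Figure D3:**
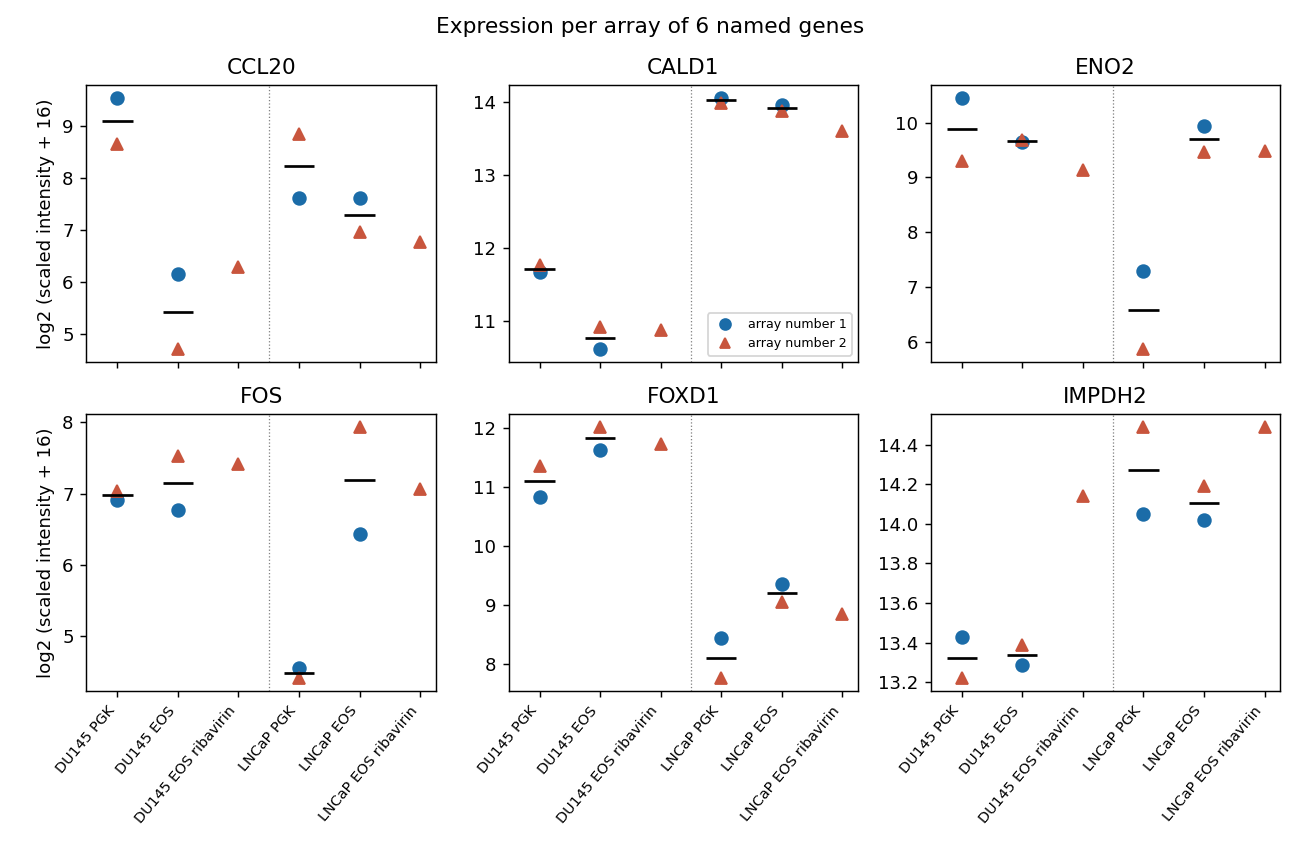
Each panel plots 1 gene as log2(scaled intensity + 16) on the vertical axis in each of the 6 groups, with circles for arrays numbered 1, triangles for arrays numbered 2 and bars for the mean of 2 arrays. CCL20 lies 3.66 lower in EOS than in PGK cells of DU145, ENO2 3.12 higher in EOS cells of LNCaP, and IMPDH2 above EOS 2 by 0.75 in DU145 and 0.30 in LNCaP after ribavirin.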

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

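The tests of explanations in this part, including the splits of the arrays, were chosen only after the result was seen, whereas the tests of the difference between the lines and the quantile normalization were chosen before. Camera with an estimated correlation called 0 lists in every comparison, also between the lines among the PGK controls. A call lost there thus decides nothing about correlation between genes. Each list below is included because camera, at the preset correlation, called the difference of a change between the lines, LNCaP minus DU145. With an estimated correlation none of these calls held, and the smallest adjusted p was 0.164 for the EOS change and 0.833 for the ribavirin change.

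The EOS change of growth and antiviral genes differed between the lines: relative to DU145, LNCaP was lower for nucleolus and ribosome biogenesis (-0.56, adjusted p = 1.11e-08), G2/M and mitosis (-0.37, adjusted p = 2.02e-07) and G1/S and replication (-0.17, adjusted p = 0.00491), and higher for interferon-stimulated genes (0.97, adjusted p = 1.08e-06). Of the 11 called lists these 4 lay in the outer 2.5% of random lists of matched signal, in the called direction, in both array numbers. In numbers 1 and 2 they were at -0.48 and -0.55, -0.35 and -0.40, -0.22 and -0.25, and 1.23 and 0.73. The 4 were grouped for that outcome, so that all of them passing holds by construction. The random lists drew genes singly, without the correlation between genes of a list, so the 2.5% is no measure of chance here. Taken list by list, a difference of the same sign in both numbers argues only against the arrays of 1 number alone as its source. Of the 11 lists 10, all but purine nucleotide synthesis, were still called after quantile normalization, which argues against signal-dependent scaling between arrays as the sole source for those lists, although relative to all genes G1/S moved from -0.23 to -0.15 and heat shock from -0.32 to -0.21. Coordinated drift between single cultures cannot be told apart from an effect of EOS selection, since the labels do not say that numbers 1 and 2 came from separate cultures, and the deviation of each number from their mean, at least the mean difference in 2 of the 11, nets genes going both ways and decides nothing. A biological difference between the lines stays open as untested, and the G1/S call was lost without DU145 EOS 1 (adjusted p = 0.212), LNCaP EOS 1 (0.117) or LNCaP PGK 2 (0.769).

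The 11 lists were parted by that outcome after it was seen, so that 0 of the other 7 lying in the outer 2.5% of random lists in both numbers holds by construction and decides nothing about the group. For each of them that comparison with random lists did not tell the arrays of 1 number alone apart from a difference between the lines. Epithelial junction genes were far lower in DU145 than in LNCaP among the PGK controls, so the size of their change in DU145 is uncertain. Epithelial junction genes differed by 0.61 (adjusted p = 0.00491, 0.537 with an estimated correlation), with 1.24 in number 1 and 0.13 in number 2, and lost the call without DU145 PGK 1 (0.105) or DU145 EOS 1 (0.287). Hypoxia and glycolysis genes differed by 0.44 (adjusted p = 0.00836, 0.554 with an estimated correlation), with 1.11 and -0.02, and lost it without DU145 PGK 1 (0.121), DU145 EOS 1 (0.287) or LNCaP EOS 1 (0.707). NF-kappaB and inflammatory genes differed by 0.51 (adjusted p = 0.0143, 0.537 with an estimated correlation), with 0.64 and 0.53, close to each other and at percentiles 96.4 and 95.8 of random lists, and lost it without DU145 PGK 1 (0.17), DU145 EOS 2 (0.353), LNCaP PGK 1 (0.0634) or LNCaP EOS 2 (0.0853). The list of eIF4E and its reported targets differed by -0.23 (adjusted p = 0.0126, 0.497 with an estimated correlation), with -0.41 and -0.20, and lost it without DU145 PGK 1 (0.055), DU145 EOS 1 (0.212) or LNCaP PGK 1 (0.058). Heat shock genes differed by -0.26 (adjusted p = 0.0143, 0.553 with an estimated correlation), with -0.09 and -0.43, and lost it without DU145 PGK 1 (0.105), DU145 EOS 1 (0.0832), LNCaP EOS 1 (0.117) or LNCaP PGK 2 (0.769). Histone genes differed by -0.47 (adjusted p = 0.0155, 0.537 with an estimated correlation), with -0.06 and -1.05, and lost it without DU145 PGK 1 (0.0589), DU145 EOS 2 (0.262), LNCaP EOS 1 (0.083) or LNCaP PGK 2 (0.769). Purine nucleotide synthesis genes differed by -0.14 (adjusted p = 0.0199, 0.537 with an estimated correlation), with -0.06 and -0.29, and lost it without DU145 EOS 1 (0.207), DU145 PGK 2 (0.0872), LNCaP PGK 2 (0.477) or LNCaP EOS 2 (0.133).

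The ribavirin change of the pluripotency list differed by -0.42 between the lines with 8 of 9 genes lower in LNCaP (adjusted p = 0.0401, 0.833 with an estimated correlation, 0.0566 with the replicate block, 0.041 with fry), and lost the call without DU145 EOS 1 (0.102), LNCaP PGK 1 (0.0594), LNCaP PGK 2 (0.0602) or LNCaP EOS 2 (0.417). The cholesterol synthesis list differed by -0.40 with 12 of 14 genes lower (adjusted p = 0.0401, 0.992 with an estimated correlation, 0.307 with the block), and lost it without DU145 EOS 1 (0.867), LNCaP PGK 1 (0.0594), LNCaP EOS 1 (0.0817), LNCaP PGK 2 (0.0602) or LNCaP EOS 2 (0.385).

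Ribavirin and EOS changes correlated negatively across genes (r = -0.196), but they share the EOS arrays, which enter with opposite sign. Unchanged simulated groups gave -0.408 (-0.45 to -0.357), but they were drawn without the pairing of arrays by number, so that this range decides nothing. With the EOS arrays split so that the changes share none, the correlation was -0.00954 (-0.00931 with PGK arrays of number 1 only, where a shared number effect cancels). It lay inside the range of -0.0683 to 0.041 of unchanged simulated groups, which were likewise drawn without the pairing. The EOS change itself barely correlated between the array pairs of a line, at 0.00913 in DU145 and 0.0827 in LNCaP. A split value near 0 can thus arise with or without a reversal. It cannot decide whether the shared EOS arrays are the source of the negative sign. Neither correlation can be read as a reversal of the EOS change across genes or as its absence.

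IMPDH2 RNA was higher in both ribavirin arrays, by 0.75 above EOS 2 in DU145 and 0.30 in LNCaP. Of the genes within 1 log2 unit of its mean signal, 0% of the others rose as much in both lines. IMPDH2 was fixed in advance as a gene to report, but this comparison was chosen after its rise was seen. Its own values also set the cutoffs, so the share is weak support. The 4 untreated arrays of a line spanned 0.20 in DU145 and 0.48 in LNCaP, so that in LNCaP the spread between arrays cannot be told apart from a rise. A feedback on the enzyme that ribavirin is known to inhibit may be a candidate explanation, and with 1 treated array per line it was not tested.

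For EOS against PGK over the mean of both lines, limma called 0 genes in the real split of the 8 arrays and 618 in the highest other, the split by array number. With a real count of 0 all 34 of 34 splits necessarily gave as many, so that this count decides nothing. At an unadjusted p under 0.05 the real split gave 289 genes in a fit to these 8 arrays, 27 of 34 splits gave as many, and the highest other gave 2958, so that chance cannot be excluded. Genes were called in 8 of the 34 splits, of which 6 part the LNCaP arrays by number and the other 2 called 1 and 3 genes. This points to a structure by number in LNCaP, where 949 genes differed by number, against 1 in DU145. Among the 8 splits that part all 4 pairs of the same number, the real one included, 3 gave at least as many as the real one at that level. The others, which exchange PGK and EOS within pairs, called 0 genes and gave at most 514. With the replicate block limma called 0, with 693 at an unadjusted p under 0.05.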

How the results depend on the processing

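The unscaled values, with and without the replicate block, the replicate number as a batch term and the split with number 1 controls were added after the data had been seen, and the other alternatives were chosen before. Of the reported values compared under an alternative, 2526 single genes and lists and 296 main values and counts kept their direction and side of the threshold or moved little. Another 172 single values were no longer past the threshold, 63 single and 60 main values moved, and 59 and 2 changed sign. Where no cause is given, the cause was not tested. Without 1 array of a group, the lone array was assumed to vary like the other groups. Moderation without trend or robust, the additive fit and the 4 arrays compared alone gave no value that had to be listed here. Genes near the background are the least certain, since the pseudocount sets the size of their change.

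With an estimated correlation, camera called 0 lists for EOS against PGK in DU145, in LNCaP, over the mean and for the difference, 0 for ribavirin in DU145 and for its difference between lines, and 0 between the lines among the PGK controls. The correlation of ribavirin and EOS changes was -0.257 with a pseudocount of 1, -0.119 with 64, -0.28 with no filter and -0.0244 above the 75th percentile. With the EOS arrays split it was -0.00954, and -0.00931 with number 1 controls, where the shared arrays are removed by construction. The correlation of EOS changes between lines was -0.135 above the 75th percentile. With no filter, 0 lists were called for the ribavirin difference between lines. All probe sets, which tests more features, gave 8629 probe sets between the lines.

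Quantile normalization turned KLF4 to 0.01, EIF4E to 0.01 and IMPDH2 to -0.01 for EOS in DU145, and gave 3 lists for ribavirin over the mean and 1 for its difference. The mean of a gene's probe sets gave TMPRSS2 0.00, EIF4E 0.05 and MDM2 0.05 for EOS in DU145, CD44 0.05 for EOS in LNCaP and KLF4 -0.43 for ribavirin over the mean. With EOS 2 as the sole ribavirin control, the mean change was -0.19 for KLF4, -0.08 for VIM, -0.02 for IMPDH1 and 0.12 for MDM2. With the replicate block these were -0.06, -0.26, -0.02 and 0.07, and with the replicate number as a batch term also -0.06, -0.26, -0.02 and 0.07. The block gave 8 lists for EOS in DU145, 9 in LNCaP, 6 over the mean and 14 for the difference. It gave 2 lists for ribavirin in LNCaP, 2 over the mean and 0 for the difference, and the batch term gave 1 in LNCaP and 1 over the mean. On the unscaled values CD44 was at -0.10, KLK3 at -0.04, IMPDH1 at -0.03 and IMPDH2 at -0.18 for EOS in DU145, where the median of all genes was -0.18, and 57 genes passed between the lines. That count comes from a fit that keeps the difference in deposited scale within each PGK group in the spread. Relative to the median of all genes, the fibroblast list in DU145 moved from 0.93 to 0.49 and the mesenchymal list in LNCaP from 0.74 to 0.49 on the unscaled values. With quantile normalization the G1/S list in LNCaP moved from -0.18 to -0.11, the neuroendocrine list over the mean from 0.24 to 0.14, and the difference of the G1/S list from -0.23 to -0.15 and of heat shock genes from -0.32 to -0.21. The unscaled values with the replicate block gave 34 genes for EOS in DU145, 51 in LNCaP, 3 over the mean and 82 for the difference. These counts were not corrected for the median change of all genes, so they may include what remains of the difference in scale.

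With each array left out in turn, genes called for EOS in LNCaP ranged from 0 to 4, and genes called between the lines from 2497 to 5061. The correlation of EOS changes between lines ranged from -0.0964 to 0.036, and that of ribavirin and EOS changes from -0.543 to 0.018. Called lists ranged from 1 to 12 for EOS in LNCaP, 0 to 10 over the mean and 6 to 14 for the difference, and for ribavirin from 1 to 8 in DU145, 0 to 1 in LNCaP, 0 to 7 over the mean and 0 to 7 for the difference. For EOS in DU145 the ranges were KLF4 -0.11 to 0.08, CD44 -0.16 to 0.33, KLK3 -0.04 to 0.31, TMPRSS2 -0.96 to 0.00, VIM -0.02 to 0.56, EIF4E -0.13 to 0.12, IMPDH2 -0.09 to 0.12, CDKN1A -0.20 to 0.00 and MDM2 -0.29 to 0.19. The fibroblast list ranged in adjusted p from 5.81e-06 to 0.962. For EOS in LNCaP the ranges were SOX2 -0.78 to 0.00, KLF4 -0.18 to 0.88, MYC -0.03 to 0.24, KLK3 -0.16 to 0.37, VIM -0.62 to 1.23, CDH1 -0.08 to 0.40, IMPDH2 -0.39 to 0.05 and CDKN1A -0.73 to 0.40. The G1/S list ranged in adjusted p from 3.2e-05 to 0.694. For ribavirin over the mean the ranges were KLF4 -0.24 to 0.28, MYC -0.08 to 0.05, VIM -0.05 to 0.24, IMPDH1 -0.02 to 0.12 and MDM2 -0.19 to 0.05. Between the lines KLF4 ranged from -0.30 to 0.10 and SOX2 from -0.14 to 0.64.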

Other observations

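The comparison of arrays numbered 2 with arrays numbered 1, and the genes set out after it, were chosen only after the data were seen, while the lists compared between the lines were fixed before. Among the PGK controls, inflammatory genes were lower in LNCaP than in DU145, with a median of -1.12 over 15 genes (camera adjusted p = 0.0164; adjusted p = 0.573 with an estimated correlation). The neutrophil-attracting chemokine CXCL2 was lower by -4.86 ± 0.51 log2 and the stress response gene IER3 by -6.40 ± 0.29. All 3 tested genes of basal epithelium were lower, LAMB3, a laminin chain, at -4.20 ± 0.54 (adjusted p = 0.0164; adjusted p = 0.249 with an estimated correlation). Drug efflux and tubulin genes had a median of -1.34, with the transporter ABCC3 at -6.35 ± 0.35 and TUBA1A at -5.82 ± 0.33, against ABCC4 at 2.38 ± 0.42 (adjusted p = 0.0164; adjusted p = 0.249 with an estimated correlation). The stem and tumour-initiating cell markers had a median of -1.12 with 9 of 10 lower (adjusted p = 0.0164; adjusted p = 0.249 with an estimated correlation).

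Several lists were higher in LNCaP. Genes of oxidative phosphorylation had a median of 0.45 with 14 of 16 higher, among them the complex I subunit NDUFV2 at 1.45 ± 0.16 (adjusted p = 0.00961; adjusted p = 0.597 with an estimated correlation). The ATF4 and unfolded protein response list had a median of 0.61 (adjusted p = 0.0134; adjusted p = 0.597 with an estimated correlation). Targets of p53, which LNCaP is known to carry in wild-type form, had a median of 0.38 (adjusted p = 0.0451; adjusted p = 0.383 with an estimated correlation), with GDF15 at 8.16 ± 0.28, CDKN1A at 1.58 ± 0.36 and MDM2 at 1.37 ± 0.26. The p53 call was lost without DU145 PGK 1 (adjusted p = 0.0674) or LNCaP PGK 1 (0.0989). Heat shock genes had a median of 0.82 (adjusted p = 0.0293; adjusted p = 0.598 with an estimated correlation; 0.0663 without DU145 PGK 1 and 0.157 without LNCaP PGK 2), with the small heat shock protein HSPB1 at 2.22 ± 0.25. Nucleolus genes had a median of 0.39 (adjusted p = 0.0451; adjusted p = 0.597 with an estimated correlation) and lost the call without any 1 of the 4 PGK arrays (0.0507 to 0.094). G2/M genes were lower, with a median of -0.37 (adjusted p = 0.0293; adjusted p = 0.634 with an estimated correlation; 0.209 without LNCaP PGK 1).

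Some lists fixed in advance were not called for EOS in either line, their mean or their difference in the unblocked fit. With the replicate block the difference of luminal and androgen-responsive genes was called (blocked adjusted p = 0.0106; adjusted p = 0.625 with an estimated correlation). Their medians in DU145 and LNCaP were -0.05 and -0.01 for stem and tumour-initiating cell markers, 0.02 and 0.60 for basal epithelium, and -0.12 and 0.27 for luminal and androgen-responsive genes. They were 0.02 and 0.05 for oxidative phosphorylation, 0.05 and 0.05 for Polycomb and chromatin, and 0.04 and 0.13 for drug efflux and tubulin. They were -0.06 and 0.18 for cholesterol synthesis, -0.12 and 0.07 for Wnt and Notch targets, and 0.18 and 0.18 for leukocyte markers. Endothelial markers, with 2 tested genes, were not tested as a list and had medians of 0.16 and 0.61.

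Within LNCaP, arrays numbered 2 differed from arrays numbered 1 in 949 genes, 522 higher and 427 lower, with the PGK and EOS group means held fixed. Luminal and androgen-responsive genes were lower in number 2, with a median of -0.40 and 17 of 19 lower (camera adjusted p = 0.000937; adjusted p = 0.771 with an estimated correlation). Among them were the ion channel TRPM8 at -2.95 ± 0.42, the prostatic acid phosphatase ACP3 at -2.45 ± 0.39 and the keratin KRT8 at -1.31 ± 0.17. The ATF4 and unfolded protein response list was higher, with a median of 0.51 and 16 of 20 higher (adjusted p = 0.00125; adjusted p = 0.771 with an estimated correlation), including ATF4 at 1.34 ± 0.15 and DDIT3 at 1.44 ± 0.22. G1/S genes were higher by 0.22 (adjusted p = 0.00282), G2/M genes by 0.17 (0.0183), oxidative phosphorylation genes by 0.19 (0.0288) and histone genes by 0.65 (0.0402), each with an adjusted p = 0.771 with an estimated correlation. Other genes of the lists that passed included TUBB6 at 3.13 ± 0.22 and PSMB8 at 3.52 ± 0.38.

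In DU145 the same comparison called 1 gene, lower in number 2, with 1113 at an unadjusted p under 0.05, and over both lines 2, with 2166. In DU145 cholesterol synthesis genes were higher in number 2 by a median of 0.54 with 12 of 14 higher (adjusted p = 4.56e-11; adjusted p = 0.632 with an estimated correlation), and inflammatory genes lower, at -0.35 with 13 of 15 lower (adjusted p = 0.000564; adjusted p = 0.632 with an estimated correlation). Fibroblast markers were at 1.08 with 5 of 5 higher (adjusted p = 0.02), G1/S genes at -0.23 (0.0201) and nucleolus genes at -0.14 (0.0226), each with an adjusted p = 0.893 with an estimated correlation. The numbers also differ in deposited scale and in the ACTB probe set ratio, so culture and RNA processing cannot be separated.

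The genes below were among those of smallest p for EOS against PGK in DU145, and none passed over all genes. PMCH was at 4.28 and 4.27 log2 in the PGK arrays, 6.62 and 6.70 in the EOS arrays and 4.30 after ribavirin. The ribavirin array lay above EOS 2 by 1.59 for CCL20, 1.55 for QPCT and 0.97 for YPEL3. These genes were picked for their EOS values and are set against the same EOS 2 array, so that no reversal can be read from them. For ribavirin in DU145 limma called 0 genes, with 250 at an unadjusted p under 0.05 and 364 with the replicate block. The probe set shared by OCT4 and related sequences had log2 values of 4.986 and 5.966 in the DU145 PGK arrays, 5.976 and 5.144 in the EOS arrays and 5.349 after ribavirin. In LNCaP it was at 6.659 and 7.561, 7.667 and 7.165, and 7.714.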
